A study of Mus musculus with 14 samples.

How the data were processed

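Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in C2C12 cells, a mouse myoblast line that forms myotubes when serum is lowered. Per the labels' protocols, cells were taken after 2 days of differentiation, cross-linked, sonicated and precipitated with 10 µg of antibody, and libraries were made from 100 ng of precipitated DNA with 18 cycles of PCR. The knockdown arm had received a small interfering RNA against the long noncoding RNA Myolinc at 10 nM before differentiation. The labels do not say whether the control cells had received a control siRNA or none. The 14 samples comprise 4 input or IgG samples, whose own signal was not analysed here, and 10 libraries with a peak list: 6 controls and 4 after Myolinc knockdown. TDP-43 had 3 control libraries and every other group had 1. Nothing in the labels says whether the 3 came from separate cultures, so p-values of tests across libraries measure only the spread between these samples, which may be technical. Tests of gene lists compare genes within 1 library, so their p-values measure no spread between samples.

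Each library came with its own peak list, called against IgG and annotated by the authors with HOMER on the mm10 build, per the submitters' processing notes and the file headers. The HOMER version, the aligner and the calling settings are not given in the sources used here. Per the file headers, each peak carried a position, a peak score, an annotation class, the nearest gene and the distance to its transcription start. The peak score is the authors' own value and was used to describe, rank or filter peaks inside 1 list. The deposited focus ratio is a fraction between 0 and 1 and was used as a description alone. Peaks on the mitochondrial genome carried no gene annotation in these lists and were left out of overlaps, class shares and gene counts.

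Within each list the scores were whole multiples of a single step, within a rounding tolerance of 0.05, once the 1% highest scores were set aside. That held for 99.2% of the scores in the Myogenin siMyolinc list and for 100% in the other 9. A step was read as the worth of 1 sequence tag, so a score divided by its step gives the tags of a peak. The number of tags in a library follows if scores are scaled to 10000000 tags, which is HOMER's default. That scaling is stated in no header or label, whereas the ratio between libraries needs only that it was the same for all. On simulated scores of the same 10 libraries, depth was recovered with a largest relative error of 0.00748%. Intervals on tags are exact Poisson intervals and intervals on shares are Wilson intervals, both at 95%. They cover counting error only, since PCR copies are not independent molecules.

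Overlap was counted at 1 bp or more and set against 1000 circular shifts of 1 list inside each chromosome. The fold is the observed overlap divided by the mean of the shifts. On simulated lists the size of TDP-43 control replicates 2 and 3 (10571 peaks in the first), a shared part of 5% was recovered as an excess of 4.99% and a shared part of 30% as 30.0%. For lists the size of the MyoD control and siMyolinc lists (71884 peaks in the first) these values were 5.01% and 29.6%. A promoter peak is a peak that the authors' annotation calls promoter-TSS, and a bound gene is the nearest gene named for that peak. The class refers to a transcript that was not matched to the named gene, so the promoter may be that of another gene. Of 22838 gene identifiers named in the lists, 22771 were found in the reference gene table, whose assembly, GRCm38, is the build named mm10, and 19649 were protein-coding. The number of genes that independent lists would share was computed among these 19649.

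Choices were made before the data were examined unless stated. The 9 fixed gene lists were muscle structure and contraction, myogenic regulators, cell cycle and DNA replication, ribosomal proteins, RNA-binding and splicing factors, extracellular matrix and fibroblast, osteoblast and adipocyte, neuronal and synaptic, and hepatocyte genes. Membership among promoter-bound genes was tested in each library with Fisher's exact test, two-sided, against 21900 protein-coding genes, with Benjamini-Hochberg adjustment over 90 tests. In 200 simulated draws over 21900 genes, an odds ratio of 4 for the muscle list gave p under 0.05 in 67.5% of draws with 400 bound genes and in 100% with 2200. Draws with no enrichment did so in 0.5% and 2% of cases. The number of list members bound after knockdown was set against 10000 random lists of genes in the same state in control, as a percentile without a p-value. For TDP-43, 3 control libraries were compared with 1 siMyolinc library by an exact two-sided permutation test, whose smallest possible p is 0.25. The other antibodies had 1 library per condition, so their differences have no replicate check and no test across libraries.

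The genes named in the text followed a fixed rule. Filip1, Myod1, Myog, Acta1, Cdkn1a and Tardbp were always named. For TDP-43 the rule took the best-ranked genes bound in all controls and not after knockdown, in all 4 libraries, and after knockdown alone. For the other antibodies it took the best-ranked genes of control alone, of siMyolinc alone and of both. Up to 4 best-ranked members of each fixed list and the 3 best peaks of a library could also be named. Symbols of predicted genes were skipped, and a part of the genes the rule allows is printed; some items are not reported here. Alternatives were stricter scores, lists of equal length (8162 peaks), exclusion of repeats, an overlap of 50% of the shorter peak, extension of peaks by 500 bp, promoter windows of 1000 and 5000 bp, exclusion of promoter peaks, another gene background and omission of each TDP-43 control library. The 50% overlap used the median widths of the lists. No genome sequence was used here, so the planned motif content and the background matched on promoter GC content were not computed. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.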

Results

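The series asked how loss of Myolinc, a long noncoding RNA that lies beside Filip1, alters chromatin binding of TDP-43 (encoded by Tardbp, a DNA- and RNA-binding protein) and whether TDP-43 occupies promoters of muscle genes. Peak lists of 4 antibodies were compared between control and siMyolinc cells. The antibodies were directed against TDP-43, the myogenic transcription factors MyoD and Myogenin, and RNA polymerase II phosphorylated at serine 2 of its C-terminal domain (Pol II S2P), the elongating form. ChIP-seq does not measure the Myolinc transcript, so the knockdown itself was not checked here. The control lists held 29703, 10571 and 8162 peaks for TDP-43 replicates 1 to 3, 71884 for MyoD, 115000 for Myogenin and 10716 for Pol II S2P. The siMyolinc lists held 24964 peaks for TDP-43, 109541 for MyoD, 20453 for Myogenin and 116064 for Pol II S2P. Except for control TDP-43, no group had a replicate.

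If peak scores are scaled to 10000000 tags, control TDP-43 replicates 1 to 3 held 1394414, 1086957 and 962386 tags and the control Pol II S2P library 1455043. The other 6 libraries held between 3040124 (Myogenin siMyolinc) and 3774952 tags (Pol II S2P siMyolinc), with 3253048 in the siMyolinc TDP-43 library. Knockdown and depth therefore changed together for TDP-43 and Pol II S2P. Peaks were called on few tags, with a median of 6 to 8 per peak in the control TDP-43, Pol II S2P and MyoD lists and 7 in the siMyolinc TDP-43 list. The median was 137 in the siMyolinc Myogenin list and 24 in the siMyolinc MyoD list. These last 2 lists also had narrow peaks of 75 bp, against 217 to 249 bp in the others, and on the same assumption held 92.8% and 81.4% of their tags inside peaks. The peaks covered 1.53 Mb in the siMyolinc Myogenin list and 8.21 Mb in the siMyolinc MyoD list.

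**Figure D1:**
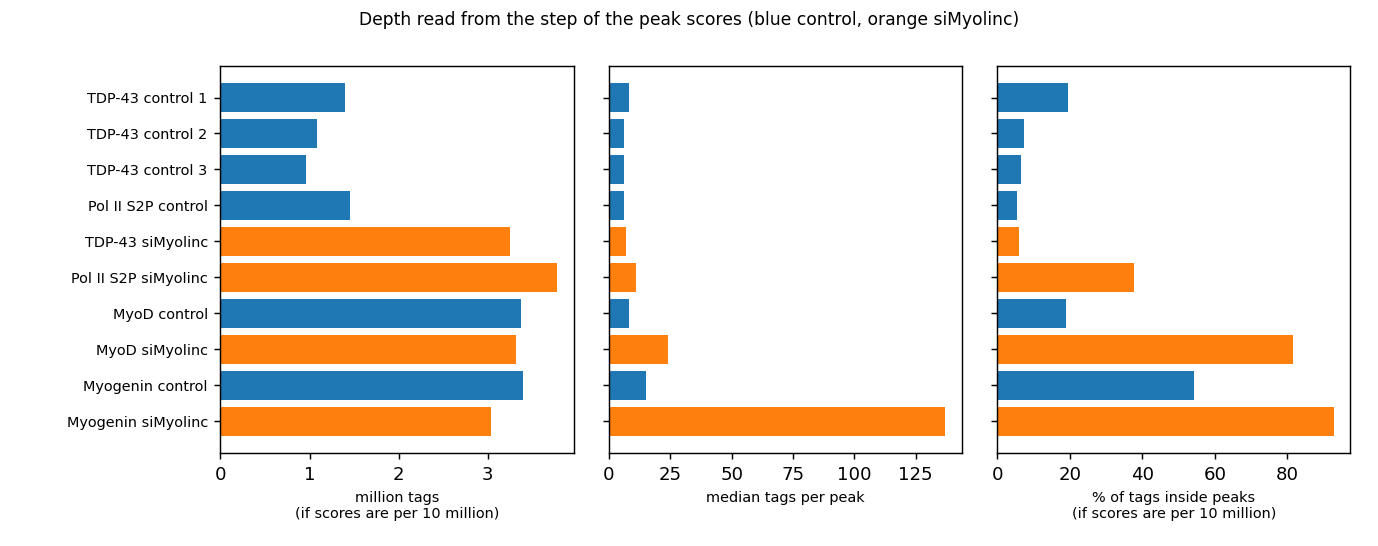
Horizontal bars give, for each of the 10 libraries, the number of tags, the median number of tags per peak and the percentage of tags inside peaks (blue control, orange siMyolinc; the tag number and the percentage assume scores per 10000000 tags). Control TDP-43 and Pol II S2P libraries hold at most 1455043 tags, and the siMyolinc Myogenin list stands apart with a median of 137 tags per peak.

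The best-scoring regions of the control TDP-43 and Pol II S2P lists were satellite repeats. In all 3 TDP-43 control libraries and in Pol II S2P control, the 2 leading peaks lay in the satellite cluster of chromosome 2, at 98662563 to 98662781 and 98667023 to 98667241 in replicate 2 (mm10), with 3670 and 2287 tags there. The same cluster held the 2 leading peaks of the siMyolinc MyoD list (317 and 315 tags). It also held the leading peak of the siMyolinc Myogenin list (628 tags), so it was not particular to the control TDP-43 and Pol II S2P lists. In the siMyolinc TDP-43 and control MyoD lists the 3 best peaks lay on the mitochondrial genome, for example at 11052 to 11268 in the former with 433 tags. Introns of Sfi1 on chromosome 11 held leading peaks of replicate 1 (3193176 to 3193424, 408 tags), of the control Myogenin list (3165900 to 3166118, 68 tags) and of the siMyolinc Pol II S2P list (3184441 to 3184659, 76 tags). Another intron of Sfi1 held 1 of the 3 best peaks of the siMyolinc Myogenin list (3149883 to 3149957, 451 tags).

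The first comparison asked how far separate TDP-43 libraries found the same places. They shared many positions. Replicate 1 overlapped 37.6% of the replicate 2 peaks (95% interval 36.7 to 38.5%) and 39.8% of the replicate 3 peaks (38.7 to 40.8%), which was 62.9-fold and 65.9-fold over circular shifts. Replicates 2 and 3 overlapped in 35.7% of the replicate 3 peaks, 174-fold over shifts. Of the replicate 1 peaks, 1565 (5.27%) were overlapped by both other replicates, and 33.4% of these lay in exons, 30.9% between genes, 23.1% in introns and 5.62% at promoters. Replicate 1 held more peaks than the other replicates combined. The median fold over pairs was 65.8 with all peaks, 103 with peaks at or above the median score, 113 with lists of equal length, 110 with an overlap of 50% of the shorter peak and 16.1 with peaks extended by 500 bp.

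The second comparison asked how promoter occupancy of TDP-43 changed after Myolinc knockdown. Promoter peaks made up 4.84 ± 0.436% of control TDP-43 peaks (SD, n = 3) and 2.53% of siMyolinc peaks (95% interval 2.34 to 2.73%), and all 3 control libraries lay above the siMyolinc library. Exon peaks made up 22.8 ± 3.59% in control (SD, n = 3) and 6.93% after knockdown, and CpG islands 4.46 ± 1.06% and 0.821%. Intergenic peaks made up 37.3 ± 1.83% in control (SD, n = 3) and 46.9% after knockdown. The exact two-sided permutation test of 3 libraries against 1 gave p = 0.25 for each of these 4 shares, the smallest value it can give, so none can pass 0.05. In the Pol II S2P lists exon peaks made up 21.4% in control and 3.76% after knockdown, and promoter peaks 3.76% and 2.00%. The control and siMyolinc libraries of both antibodies also differed in depth.

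**Figure D2:**
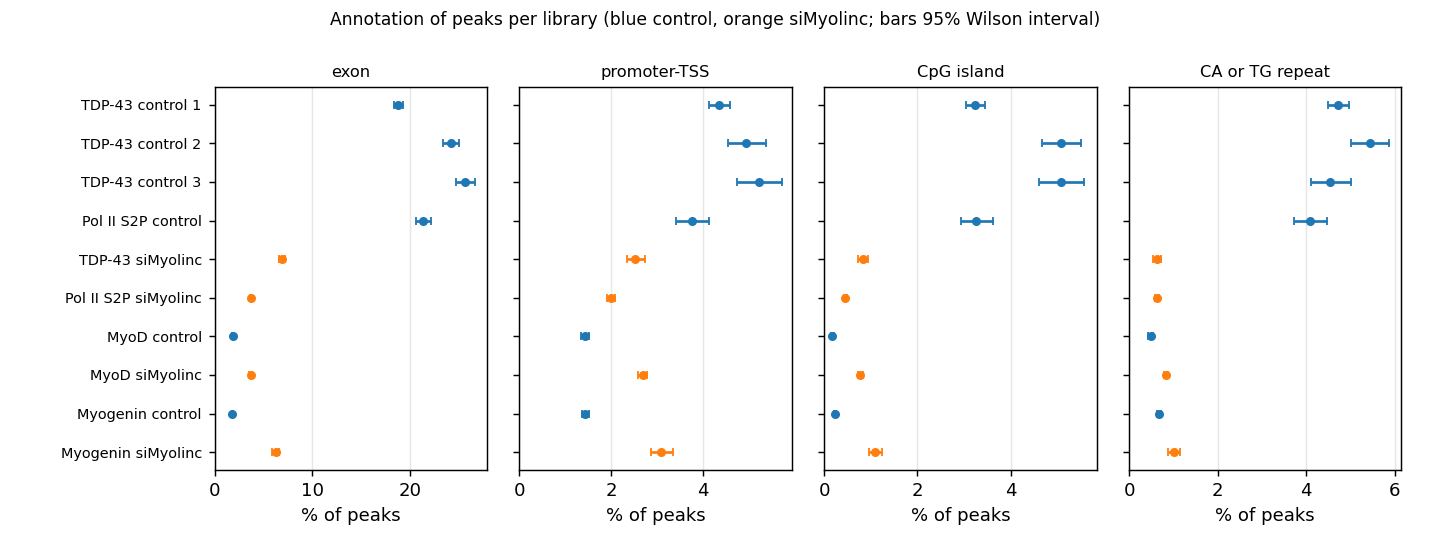
Points give the percentage of peaks annotated as exon, promoter-TSS, CpG island and CA or TG repeat in each of the 10 libraries, with 95% Wilson intervals (blue control, orange siMyolinc). The 3 control TDP-43 lists and the control Pol II S2P list lie between 18.8% and 25.6% for exons, above the other 6 lists, whose highest value is 6.93%.

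A promoter peak was listed for 1267, 519 and 421 genes in control replicates 1 to 3 and for 628 genes after knockdown. The siMyolinc list shared 107, 41 and 35 genes with them. Among protein-coding genes it shared 95, 35 and 30, where independent lists would share 31.0, 12.9 and 10.1. Of 79 genes bound in all 3 controls, 74 had no promoter peak in the siMyolinc list and 5 did: Myt1l and Tlx3 (transcription factors of the nervous system), Lrat (vitamin A storage), Tmprss12 (a serine protease) and Aldh7a1 (an aldehyde dehydrogenase). The best-ranked of the 74 included Pisd-ps2, Ppp1r3d (a glycogen-targeting subunit of protein phosphatase), Oasl1 (an interferon-induced gene), Foxl2os, Irx6 (a homeobox gene), Il12rb2 (an interleukin receptor subunit), Slc14a1 (a urea transporter) and Qrfpr (a neuropeptide receptor). The Ppp1r3d peak on chromosome 2 (178413469 to 178413717 in replicate 1, 870 bp downstream of the start) held 20, 11 and 11 tags in replicates 1 to 3. Its promoter class was not matched to Ppp1r3d and may belong to another gene. The Oasl1 peak on chromosome 5 (114922356 to 114922604, at -760 bp from the start) held 12, 18 and 11 tags. Promoter peaks of 489 genes appeared in the siMyolinc list and in no control list. They were led by Pank4, Ppp2r5a (a regulatory subunit of protein phosphatase) and Npy1r (a neuropeptide Y receptor), with 15, 15 and 14 tags, followed by Brip1 and Nbn (DNA repair), each with 13 tags (interval 6.92 to 22.2). The number of bound genes was 736 ± 463 in control (SD, n = 3) and 628 after knockdown, with p = 1 in the exact two-sided permutation test. Between controls, replicate 1 contained 41.8% and 43.7% of the genes of replicates 2 and 3, whereas the siMyolinc list contained 7.90% and 8.31% of them. The ratio of siMyolinc to control genes was 0.854 with all libraries, 1.34 without replicate 1, 0.538 with lists of equal length, 1.03 with peaks at or above the median score and 1.08 with promoters of 5000 bp, so its direction is not settled.

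The third comparison asked whether TDP-43 shared positions with MyoD, Myogenin and Pol II S2P. In control cells TDP-43 peaks coincided most with Pol II S2P peaks, which overlapped 12.0%, 19.7% and 21.6% of the peaks of replicates 1 to 3, on average 84.4-fold over shifts. MyoD peaks overlapped 2.76%, 3.42% and 3.61% of them (2.42-fold on average) and Myogenin peaks 5.33%, 6.01% and 6.22% (2.82-fold). Of the 1565 peaks shared by the TDP-43 controls, 592 (37.8%) met a Pol II S2P peak, 132 (8.43%) a Myogenin peak and 87 (5.56%) a MyoD peak. Inside siMyolinc cells, 6.57% of TDP-43 peaks met Pol II S2P (3.18-fold), 3.68% met MyoD (2.83-fold) and 0.994% met Myogenin (4.09-fold). All 90 ordered pairs of lists exceeded every one of their 1000 shifts, so exceeding the shifts does not single out any pair. The control Myogenin list overlapped 2.58% of control MyoD peaks, 1.25-fold over shifts, the lowest fold among the control pairs. Without repeats the folds of TDP-43 with MyoD, Myogenin and Pol II S2P were 4.06, 4.71 and 134, and with peaks extended by 500 bp they were 1.36, 1.48 and 19.5. With an overlap of 50% of the shorter peak the fold with Pol II S2P was 148.

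**Figure D3:**
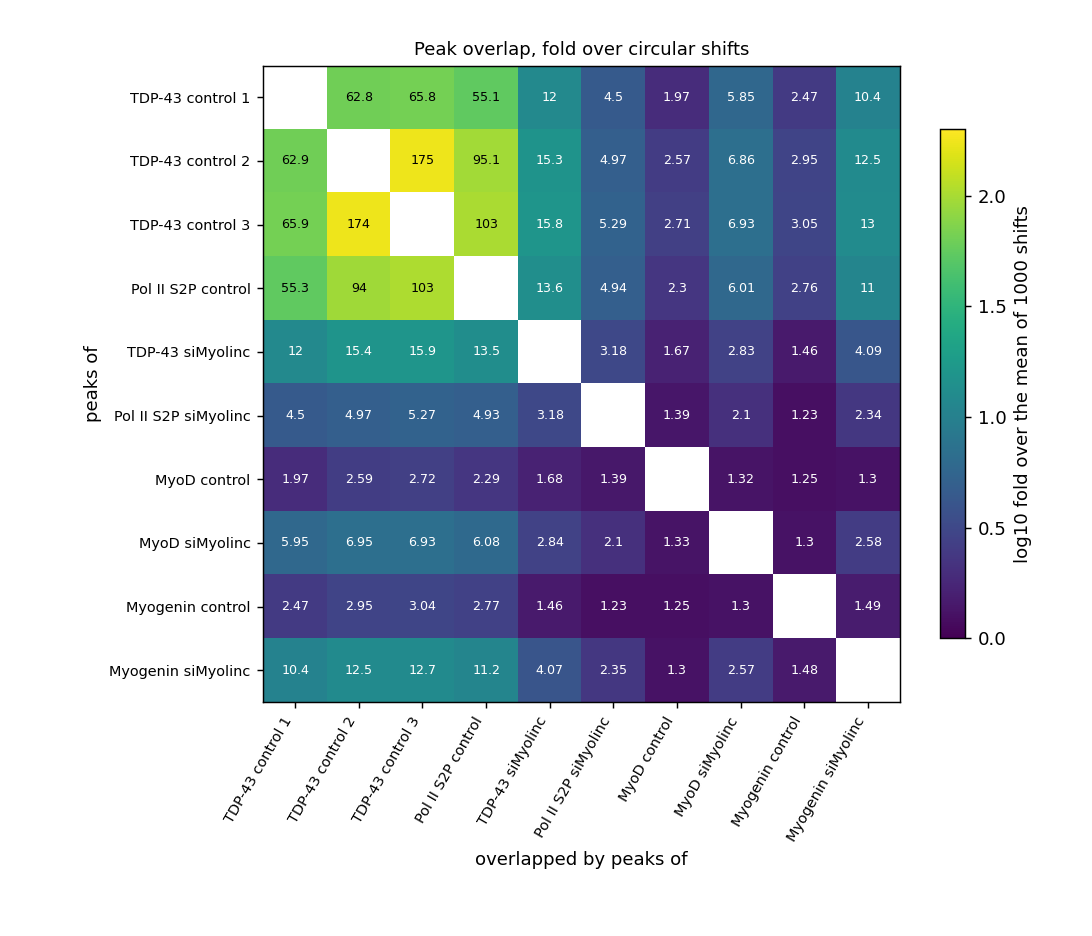
Each cell gives the fold overlap of the peaks of the row library with the peaks of the column library over the mean of 1000 circular shifts, coloured on a log10 scale. The 3 control TDP-43 lists and the control Pol II S2P list form a block between 55.1-fold and 175-fold, above all other pairs.

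The fourth comparison asked how many control peaks were found again after knockdown. The siMyolinc TDP-43 list overlapped 5.88%, 7.08% and 7.36% of the peaks of control replicates 1 to 3, on average 14.4-fold over shifts, below the 62.8-fold to 175-fold between control replicates. For Pol II S2P, 10.5% of control peaks were found again (4.94-fold). For MyoD the value was 1.77% (1.68 to 1.87%, 1.32-fold) and for Myogenin 0.355% (0.322 to 0.391%, 1.49-fold). Both folds were lower than those with the control TDP-43 and Pol II S2P lists. They were above the 1.25-fold overlap between the control MyoD and control Myogenin lists. Control MyoD peaks met the control TDP-43 lists 1.97-fold to 2.72-fold and control Pol II S2P 2.29-fold. Control Myogenin peaks met them 2.47-fold to 3.04-fold and 2.77-fold. Folds with the remaining lists were 1.25 to 1.68 for control MyoD and 1.23 to 1.46 for control Myogenin. The control Pol II S2P list overlapped the siMyolinc TDP-43 list 13.6-fold, within the range of the 3 control TDP-43 lists with it, 12.0-fold to 15.8-fold. With lists of equal length the folds were 24.6 for TDP-43, 11.4 for Pol II S2P and 2.90 for MyoD, and without repeats they were 24.3 for TDP-43, 9.12 for Pol II S2P, 1.99 for MyoD and 2.29 for Myogenin. With an overlap of 50% of the shorter peak the fold was 21.8 for TDP-43, and with peaks extended by 500 bp it was 4.46 for TDP-43 and 2.19 for Pol II S2P.

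The fifth comparison asked which promoters were bound by MyoD, Myogenin and Pol II S2P before and after knockdown. Genes with a MyoD promoter peak numbered 1016 in control and 2758 after knockdown, with 142 in both. Of these 131 were protein-coding, where independent lists would share 110. In control alone the best-ranked included Olfr1300-ps1 (an olfactory receptor pseudogene), Rars2 (a mitochondrial tRNA ligase), Tmem107 and Tuba4a (a tubulin), with 23, 21, 20 and 19 tags. After knockdown alone they included Rab43 (a membrane traffic GTPase, 80 tags), Dsg2 (a desmosomal cadherin, 59 tags), Xpo5 (a nuclear export factor, 59 tags) and Fbxo5 (a cell cycle regulator, 57 tags). The Rars2 and Xpo5 peaks lay 522 and 717 bp downstream of the named start, so their promoter class may belong to another gene. Slc25a17, Ttc23l, Pop7, Snora33 and Dlk2 led the genes bound in both. Among these, the ranked control and siMyolinc peaks overlapped at Snora33 only, so being bound in both does not mean the same site. Genes with a Myogenin promoter peak numbered 1622 and 620, with 48 in both, and 42 protein-coding genes in both against 38.7 for independent lists. Sh3tc1 (53 tags), Serp2 (48 tags), Cacna2d1 (a calcium channel subunit, 46 tags) and Nfatc2 (a calcium-regulated transcription factor, 40 tags) were among the leaders in control. Tspan2 (390 tags), Mog (a myelin protein, 342 tags) and Timm13 (mitochondrial import, 269 tags) were among the leaders after knockdown, and Tomm20, Crispld2 and Npm2 were bound in both. Of the last group, the ranked peaks overlapped at Npm2 only. Genes with a Pol II S2P promoter peak numbered 401 and 2245, with 79 in both, and 65 protein-coding genes in both against 33.6 for independent lists. Pcdha12 (a protocadherin, 17 tags), Sptbn1 (a spectrin, 13 tags) and Krt17 (a keratin, 12 tags) were among the leaders in control, Olig2 (a glial transcription factor, 46 tags) and Podnl1 (36 tags) after knockdown, and Adgb and Scg5 were bound in both. At Adgb and at Scg5 the ranked control and siMyolinc peaks overlapped. With lists of equal length the ratio of siMyolinc to control genes turned from 0.382 to 1.49 for Myogenin and from 5.60 to 0.618 for Pol II S2P, and was 1.30 in place of 2.71 for MyoD. For MyoD it was also 1.76 with peaks at or above the median score and 1.64 with promoters of 5000 bp.

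**Figure D4:**
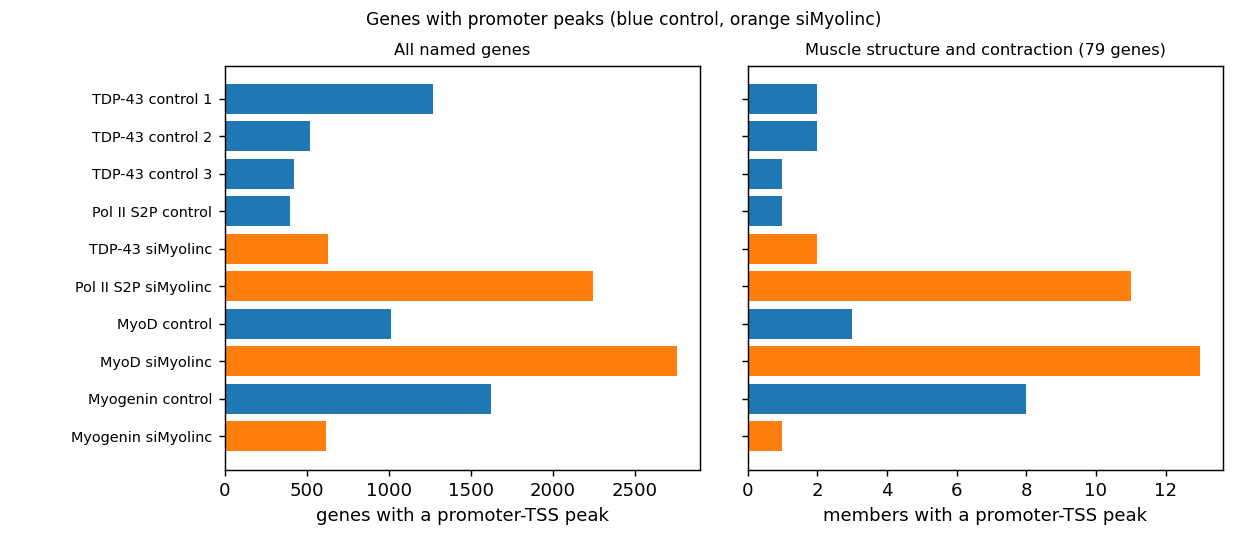
Bars give, for each of the 10 libraries, the number of genes with a promoter-TSS peak and the number of the 79 muscle structure and contraction genes among them (blue control, orange siMyolinc; no error bar, 1 library each). MyoD and Pol II S2P have more after knockdown, Myogenin fewer, and control TDP-43 lists hold 1 or 2 muscle genes each.

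The sixth comparison asked whether muscle genes and the other fixed lists were bound. Of 79 muscle structure and contraction genes, the TDP-43 controls had a promoter peak at 2, 2 and 1, and the siMyolinc list at 2. The control genes were Jph2 and Pygm in replicate 1, Tnni2 and Synpo2l in replicate 2 and Ckm (muscle creatine kinase) in replicate 3, so none recurred in a second control. Synpo2l and Mylpf were bound after knockdown. MyoD was listed at 3 muscle promoters in control, among them Tnnt1 and Mb (myoglobin), and at 13 after knockdown, led by Tcap, Myl4, Tnnt3 and Myom2. Myogenin was listed at 8 in control, led by Ttn (titin), Jsrp1, Myom1 and Mybpc2, and at 1 (Myom3) after knockdown. Pol II S2P was listed at 1 (Ckm) and 11, led by Mb, Tnnt3, Jph2 and Chrng. The muscle list was enriched in no library, with odds ratios from 0.484 to 1.66. Against random lists in the same control state, the muscle list after knockdown lay at percentile 56.6 for TDP-43, 92.6 for MyoD, 27.7 for Myogenin and 93.2 for Pol II S2P, all inside the 95% range. With lists of equal length the change in muscle genes was -1 for TDP-43 in place of 0.333, 0 for MyoD and Myogenin and 1 for Pol II S2P. With promoters of 1000 bp it was -2, 19, -11 and 17 for TDP-43, MyoD, Myogenin and Pol II S2P, and with 5000 bp -0.667, 24, -21 and 41.

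Of the 90 tests of lists, 1 passed: neuronal and synaptic genes in TDP-43 control replicate 3, at 6 of 49 members, with an odds ratio of 8.43 (adjusted p = 0.0135, Fisher's exact test with Benjamini-Hochberg adjustment). Syn2 (a synapsin), Cntnap2, Neurod1 and Nlgn1 were among them. Replicate 2 had 5 members, with Cacna1a, Camk2a, Grin2b and Syn2, an odds ratio of 5.30 and an adjusted p of 0.167 in Fisher's exact test with Benjamini-Hochberg adjustment. Replicate 1 had 3 members and the siMyolinc library 1 (Shank1). Without adjustment, 6 tests of enrichment and 1 of depletion had p under 0.05. With peaks at or above the median score 0 of the tests passed, with promoters of 1000 bp 2 and with 5000 bp 9. Ribosomal protein genes had a TDP-43 promoter peak in none of the 3 controls and at 6 of 75 members after knockdown, among them Rpl12 and Rps19 with 9 tags each, at percentile 99.7 of random lists. For Pol II S2P they also went from 0 members in control to 8 after knockdown, at percentile 72.9. A rise from 0 was therefore not particular to TDP-43. MyoD was listed at 7 and 10 of these members and Myogenin at 8 and 3, in control and after knockdown. Myogenic regulators had a MyoD peak at 2 of 47 members in control and at 11 after knockdown, led by Srf, Filip1, Tcf12 and Myocd, at percentile 99.1. The siMyolinc MyoD list is a single library with narrow peaks of 75 bp, and it overlapped control MyoD peaks only 1.32-fold over shifts. Ribosomal protein genes with TDP-43 and myogenic regulators with MyoD were the 2 of 36 combinations of antibody and list above the 95% range, where chance gives up to 0.9. None lay below it. For TDP-43, myogenic regulators went from a mean of 2.33 to 1 member (Rbm24), cell cycle genes from a mean of 0.333 to 0 members, RNA-binding and splicing factors from 0.333 to 0, hepatocyte genes from 0.667 to 0, extracellular matrix genes from 2 to 1 (Timp1) and osteoblast and adipocyte genes from 1.67 to 1 (Plin4).

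At the genes named in advance, promoter peaks differed between antibodies, and those of TDP-43 held 8 tags or fewer. Filip1 (chromosome 9, 79805018 to 80012851) had a MyoD promoter peak in control (79977770 to 79978000, 7 tags, interval 2.81 to 14.4) and after knockdown (79977837 to 79977911, 39 tags, 27.7 to 53.3). It also had a Myogenin promoter peak after knockdown with 172 tags, and no TDP-43 promoter peak in any library. Myod1 (chromosome 7, 46376474 to 46379092) had a promoter peak in TDP-43 control replicates 1 and 2, at -115 and -101 bp from its start, with 8 and 6 tags, in Pol II S2P control with 6 tags and in Myogenin control with 9 tags. No Myod1 promoter peak was listed in TDP-43 replicate 3 or in any siMyolinc list. Myog (chromosome 1, 134290004 to 134292548), which encodes Myogenin, had a promoter peak in TDP-43 control replicate 1, at -232 bp with 8 tags, and an exon 1 peak in Pol II S2P control with 5 tags. Acta1 (skeletal actin, chromosome 8, 123891758 to 123894775) had TDP-43 peaks in its exons in replicate 1 (12 tags), replicate 2 (10 tags) and siMyolinc (6 tags), and 2 Pol II S2P promoter peaks after knockdown. Cdkn1a, a cell cycle inhibitor on chromosome 17, had a Pol II S2P promoter peak after knockdown, at -913 bp with 15 tags. Tardbp had no promoter peak in any of the 10 lists.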

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

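The tests of a library class given here were chosen after the overlaps had been seen, while those of repeats and of exons, promoters and CpG islands were written down before their values were seen, the latter as a setting added after other results. Shares of peaks and numbers of genes differed in direction between antibodies when siMyolinc lists were set against control lists, and these differences were not tested. The share of promoter peaks after knockdown, relative to control, was 1.88 for MyoD and 2.15 for Myogenin, but 0.523 for TDP-43 and 0.531 for Pol II S2P. The share of exon peaks was 1.99 and 3.40 for MyoD and Myogenin, but 0.303 and 0.176 for TDP-43 and Pol II S2P. The number of genes with a promoter peak was 2.71 times the control for MyoD and 5.60 times for Pol II S2P, but 0.382 times for Myogenin. With lists of equal length these were 1.30 for MyoD, 0.618 for Pol II S2P and 1.49 for Myogenin, so the last 2 turned.

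Control TDP-43 lists overlapped the control Pol II S2P list 84.4-fold over shifts and the siMyolinc TDP-43 list 14.4-fold. Repeats alone do not account for this contrast, since without them the folds were 134 and 24.3. The overlap with Pol II S2P did not rest on exons, promoters and CpG islands alone, since its fold was 81.3 among plain intron and intergenic peaks. The fold with the siMyolinc TDP-43 list was not computed among those peaks. A part of these classes in the contrast was therefore not tested. A library class shared by the control TDP-43 and Pol II S2P libraries, whatever the antibody, remains a candidate explanation, because the control Pol II S2P list overlapped the siMyolinc TDP-43 list 13.6-fold, inside the 12.0-fold to 15.8-fold range of the control TDP-43 lists. These 4 libraries are also the shallowest, and no library of that kind was made after knockdown. Effects of Myolinc knockdown on TDP-43 and Pol II S2P, true co-occupancy and a mislabelled library stay open and were not separately tested.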

How the results depend on the processing

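Of 125 alternatives to 18 results, 71 stayed within the spread without reversing, 46 moved and 8 reversed. Among the 71 are 2 in which the change in TDP-43 muscle genes was 0 (scores at or above the list median, and without replicate 3), which has no direction. The spread was 1 SD over control libraries or pairs of them, 50% of the width of the counting interval for overlaps of 1 library and for muscle genes, and 1.5 times for ratios of bound genes and for list tests, while the promoter share was held to direction alone; where a result changed, the cause was not tested. The lower promoter share of TDP-43 after knockdown kept its direction under all 8 alternatives run, with differences from -2.12 to -8.80 percentage points, and p could not fall below 0.25, or 0.333 with 2 controls. Without 1 TDP-43 control library, the replicate overlap ranged from 62.9-fold to 173-fold, the ratio of promoter-bound genes from 0.703 to 1.34, TDP-43 overlap with MyoD from 2.27-fold to 2.66-fold, with Myogenin from 2.71 to 2.99 and with Pol II S2P from 75.3 to 99.5, control TDP-43 peaks found again from 13.7-fold to 15.7-fold, and the change in muscle genes from 0 to 0.5.
With equal list lengths, TDP-43 overlap with MyoD was 3.15-fold and with Myogenin 3.61-fold, control peaks found again were 24.6-fold for TDP-43, 2.90 for MyoD, 1.25 for Myogenin and 11.4 for Pol II S2P, ratios of promoter-bound genes were 0.538, 1.30, 1.49 and 0.618, and changes in muscle genes -1, 0, 0 and 1, in the same order.
With scores at or above the list median, TDP-43 overlap with Pol II S2P was 121-fold, peaks found again were 19.2-fold for TDP-43, 1.74 for Myogenin and 6.92 for Pol II S2P, ratios of bound genes were 1.03 for TDP-43 and 1.76 for MyoD, and 0 list tests passed.
Without repeats, TDP-43 overlap with MyoD, Myogenin and Pol II S2P was 4.06-fold, 4.71-fold and 134-fold, and peaks found again were 24.3-fold, 1.99, 2.29 and 9.12 for TDP-43, MyoD, Myogenin and Pol II S2P.
With an overlap of 50% of the shorter peak, TDP-43 overlap with the 3 partners was 3.28-fold, 3.93-fold and 148-fold, and peaks found again 21.8-fold for TDP-43 and 6.99 for Pol II S2P. With peaks extended by 500 bp these values were 1.36, 1.48 and 19.5, and peaks found again 4.46, 1.19, 1.16 and 2.19 for TDP-43, MyoD, Myogenin and Pol II S2P.
With promoters within 1000 bp, changes in muscle genes were -2, 19, -11 and 17 for TDP-43, MyoD, Myogenin and Pol II S2P, and 2 list tests passed. With 5000 bp they were -0.667, 24, -21 and 41, ratios of bound genes were 1.08 for TDP-43 and 1.64 for MyoD, and 9 list tests passed.
The SD over pairs of control TDP-43 libraries was wide (64.8 around 65.8-fold), so their overlap counted as kept even at 16.1-fold with peaks extended by 500 bp. Overlap among plain intron and intergenic peaks was chosen after seeing the data. Motif content and the background matched on GC content were not run, as no genome sequence was used here. No paired analysis was possible because no compared groups share more than 1 replicate number. Depth limits these results, since the median peak of the control TDP-43 lists held 6 to 8 tags and an unlisted peak was not shown to be absent.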

Other observations

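The gene-body counts in this part, the test of few starting molecules and all tests of CA and TG repeats were chosen after seeing the data. Exon peaks and all peaks were counted in the gene bodies of the 9 lists and set against random genes of the same gene length. For exon peaks of the muscle structure list the ratio was 2.37, 2.20 and 2.38 in TDP-43 control replicates 1 to 3 and 2.40 in the siMyolinc TDP-43 list, and it was above the 95% range of 2000 random lists in these 4. Ratios were 3.23 and 1.99 for MyoD, 2.92 and 3.37 for Myogenin and 2.04 and 2.13 for Pol II S2P in control and siMyolinc, above the range in all but control Pol II S2P. For all peaks the muscle list was above the range in TDP-43 control replicate 1 (1.55) and control Myogenin (1.42) and inside it in the other 8 libraries. The neuronal and synaptic list was above the range for all peaks in 9 of 10 libraries, with ratios from 1.42 (siMyolinc Pol II S2P) to 2.19 (TDP-43 control replicate 2), and inside it in TDP-43 control replicate 3 (1.93). RNA-binding and splicing factors were below it in TDP-43 control replicate 1 (0.434) and siMyolinc Pol II S2P (0.667), cell cycle genes in TDP-43 control replicate 2 (0.423), hepatocyte genes in siMyolinc TDP-43 (0.382) and ribosomal protein genes in the 3 TDP-43 controls and control Pol II S2P (0 to 0.209). Other lists also exceeded the exon range, RNA-binding and splicing factors in control MyoD (2.84) and extracellular matrix genes in siMyolinc Pol II S2P (2.39), and RNA-binding and splicing factors were below it in TDP-43 control replicate 1 (0.372). Lists were matched on gene length and not on exon length. Ryr1, the calcium release channel, was singled out after its values were seen and held 7, 3 and 3 exon peaks in the TDP-43 controls. Ribosomal protein genes held 1, 0 and 0 exon peaks in the TDP-43 controls, where random lists gave 10.7, 5.56 and 3.97. They were also below the range in control Myogenin (0 against 3.77), siMyolinc MyoD (2 against 7.93) and control and siMyolinc Pol II S2P (0 against 4.70 and 1 against 6.81), and inside it in the other 3 libraries, so this was not particular to TDP-43.

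The siMyolinc Myogenin list held most of its tags in narrow peaks of many tags. It overlapped the control Myogenin list 1.48-fold over shifts. By this value, few starting molecules copied many times cannot be told apart from other causes. The control Myogenin list itself met the control MyoD list only 1.25-fold. The condition drawn from that fold was added to the test after the value of 1.48 was seen. Before it was added, the test had favoured few starting molecules. Binding gained or kept after Myolinc knockdown was tested as more overlap for peaks with more tags. The 5111 peaks with most tags overlapped control Myogenin peaks in 2.25% of cases (1.88 to 2.69%). That was above the upper limit of the 5110 with fewest (1.64%, 1.33 to 2.03%). These intervals overlap, so kept binding rests on a small difference. Sites gained after knockdown would be absent from the control list, so the test cannot address gained binding. Few starting molecules, kept binding and gained binding all stay open. The siMyolinc Myogenin list also overlapped the control TDP-43 lists 10.4-fold to 12.7-fold and the control Pol II S2P list 11.2-fold, which none of these explanations foresaw. It overlapped the siMyolinc TDP-43, MyoD and Pol II S2P lists 4.07-fold, 2.57-fold and 2.35-fold. Only the control MyoD list gave a lower fold (1.30) than the control Myogenin list.

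Control TDP-43 lists held 4.90 ± 0.468% of peaks in CA and TG repeats (SD, n = 3) against 0.621% in the siMyolinc list, a ratio of 7.89, and GA and TC repeats differed more, with 1.37% against 0.100%, a ratio of 13.7. Loss of binding of TDP-43 to TG-rich sequence would lower the ratio of CA and TG to GA and TC repeats with TDP-43 relative to other antibodies, but the ratio rose with every antibody, 1.71 times with TDP-43 (1.11 to 2.63), 1.85 with MyoD, 2.26 with Myogenin and 1.93 with Pol II S2P, and the TDP-43 interval spans the others, so loss and no loss cannot be told apart. Earlier forms of the test were replaced after their values were seen. Against other control lists it first went against binding to TG-rich sequence. It was undecided there once counting intervals were used (MyoD 3.95, 3.13 to 4.99, against 3.23 to 3.80 with TDP-43). Against the TDP-43 controls alone it again went against that binding, but ignored the rise in all antibodies. In control the ratio was 3.16 with Myogenin (2.74 to 3.65). With Pol II S2P it was 2.02 (1.72 to 2.38), below the TDP-43 controls. A library class shared by the control TDP-43 and control Pol II S2P libraries, which the labels do not describe, is consistent with the CA and TG share of control Pol II S2P, 6.04 times the higher of MyoD and Myogenin. Both explanations stay open.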
